A study of Oryza sativa with 2 samples.

How the data were processed

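The samples were 1 chromatin immunoprecipitation library made with an antibody against FLAG and 1 input library, both from rice plants in which a mutant of OsbHLH002 carried a genomic OsbHLH002 copy with a FLAG tag. Per the labels' protocols, plant material was fixed with 1% formaldehyde for 15 min, and nuclei were sonicated to fragments of 300 to 500 bp. The tissue and growth conditions are not given in the sources used here. Groups were taken from the sample labels. The input had no table of its own here and entered only through the background of the peaks.

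Per the submitters' processing notes, the tools were Bowtie2 2.4.2, SAMtools, Picard and MACS2 2.2.7.1. The genome build, the annotation release, the alignment filters and the calling threshold are not given in the sources used here. The gene identifiers are of the LOC_Os type, and coordinates are as deposited, written counting from 1. The authors deposited 1 list of peaks of the IP library, joined to gene models. The fold enrichment in it is a linear ratio of IP to local background at the summit, per the file headers and the form of the peak caller's output. The deposited p and q values are given as −log10, and the deposited score was 10 times the −log10 p without its decimals in 14706 of 14709 entries. These values are the authors' own. They were used to describe, rank and filter peaks within this list, to compare groups of its genes, and to recover fragment counts.

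Each entry was 1 gene whose window of 2000 bp to either side of its start overlapped a peak, and each gene had 1 peak. The 14709 entries held 12487 distinct peaks: 10355 were on 1 gene, 2044 on 2 and 88 on 3 or 4. Peak numbers ran to 22071, so 56.6% of them were on a gene in the list, and the other 9584 were not analysed here. In 814 pairs of a gene and a listed peak, the peak overlapped the window of the gene but the gene carried another peak. In 443 of these pairs the peak left out was the stronger, so the peak of a gene was not always its strongest. A peak can be in several such pairs. The lowest deposited −log10 p was 2.01. Genes lay on 12 chromosomes, with 5 genes on unplaced sequence.

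Fragment counts were recovered from the deposited values. The peak caller's fold is (pileup + 1) / (background + 1) and its p is the upper tail of a Poisson distribution, so each pair of values was solved for the whole-number pileup and the background. A single whole-number solution was found for 12486 of 12487 peaks, with a tolerance on the −log10 p of 0.0001 times its value plus 0.0002. The exception, at the OsbHLH002 gene, was solved without the whole-number condition, with bounds from the rounding of the fold. The lowest background, 4.44 fragments, was shared by 3257 peaks (26.1%) and was taken as the genome-wide background. The other backgrounds moved in steps of 0.472, which is the weight of 1 input fragment, so the input was 2.12 times as deep as the IP. Of 9229 backgrounds above the genome-wide level, 5787 were whole multiples of that step within a small fixed tolerance, and 2694 of the others were so at the caller's 1 kb window. The fragment length that gave this was 229 bp, and the depth came to 19.4 IP and 41.0 input fragments per kb of the caller's genome size. Library totals are not given in the sources used here. At this depth the lowest pileup among the peaks was 10 fragments and the median 20, so single peaks near the threshold rest on few fragments. The deposited p and q values cover counting error only, since amplified fragments carry no molecular identifiers and there was no replicate. The intervals and p-values of the tests here treat peaks or genes as separate units. They cover neither the counting error of fragments nor the spread between plants.

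Before the data were examined, the design, the rule for named genes, 7 gene lists (46 genes) and 25 keyword classes were fixed, with the lists' gene identifiers written from general knowledge. The list of peaks does not pair most of these identifiers with symbols, and 0 of its identifiers were found among the 39387 entries of the reference gene table, so genes are named by identifier and description except where the list gives a symbol (the CESA, CSLF, OsWAK and OsFBX genes). OSH1 and OsbHLH002 stand for LOC_Os03g51690, described as a homeobox gene, and LOC_Os11g32100, described as an inducer of CBF expression. The rule named OSH1 and OsbHLH002 in any case. It then took all members of the secondary wall lists with a peak and up to 4 members of each other list by fold. Last came the 20 genes of highest fold whose summit lay in the gene or within 2 kb upstream, 1 gene per peak. Genes of the keyword classes named with a value were chosen as leaders of their class after their values were seen.

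Several planned tests were not run, because no genome sequence or full gene annotation of the build was used here. These were the share of summits in promoters against the genome, E-boxes and other motifs and hexamers at summits, motif by peak strength, and Fisher's exact test of lists and classes against all annotated genes. In their place, after the data were seen, the following were chosen. The share of members with a peak was compared over the 7 lists by permuting genes over lists (chi-square statistic, 100000 resamples) and between the monolignol list and both secondary wall lists by Fisher's exact test. The strength of each class of at least 5 genes was compared with all other genes in the list by a permutation test of the mean rank of the fold (100000 resamples, two-sided, Benjamini-Hochberg over 25 classes). Summit positions were compared by exact binomial and Fisher tests, two-sided. Acronyms in the keyword classes were matched as whole words in their own case, a rule tightened after the matched descriptions of a looser one had been read. The peroxidase class takes every gene described as a peroxidase. Broad strong peaks were defined as fold 12 or more after the folds were seen. Peaks and genes in 1 list are not replicates, and genes that share a peak share its fold.

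The recovery and the class test were tested on simulated data. The true pileup was recovered for 2000 of 2000 simulated peaks. These were made with the formulas that the recovery solves, so they test the solving and not whether the peak caller used those formulas. They also did not reach the highest folds of the list or the background at the OsbHLH002 gene. With 14709 genes, 19 of 20 classes of 60 genes shifted 1.25-fold were called, and 0 of 20 unshifted classes. These classes were random and of a single size. The simulation therefore does not cover the small classes, down to 6 genes, or classes whose genes share peaks. Alternatives were a fold at or above the median, a stricter q, other gene assignments, q at or under 0.05, removal of peaks of fold 12 or more, the lists without OsbHLH002, pileup in place of fold, 1 gene per peak and ranks within 10 bins of gene length. Pileup is the IP count alone, without correction for the local background. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.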

Results

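OsbHLH002 is a basic helix-loop-helix (bHLH) transcription factor of rice, described in the annotation as an inducer of CBF expression, the family that in Arabidopsis switches on the DREB1 (CBF) cold genes. The study asked where this protein sits on the rice genome, in plants in which a mutant of the gene carried a genomic copy fused to the FLAG epitope. Chromatin was fixed, sheared, precipitated with an antibody against FLAG (the IP, 1 library) and sequenced beside its input (1 library). The list analysed here held 12487 peaks of the IP over the input, placed on 14709 genes whose start lay within 2 kb of a peak. With 1 IP there was no replicate, so every test below describes this list and not the spread between plants.

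Most peaks were modest. The median fold enrichment was 3.13 (quartiles 2.57 and 4.10), the median width 445 bp (quartiles 316 and 673 bp), and the median −log10 q 3.85. The median summit held 20 IP fragments (quartiles 16 and 26) over a local background of 5.19 fragments. The weakest peaks were close to background: 1237 peaks (9.91%), on 1461 genes, had a q above 0.05, and the highest q was 0.297. At a q of 0.05 or less, 11250 peaks on 13248 genes were left.

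OSH1, the KNOX homeobox gene named with OsbHLH002 in the title of the study and known for its role in the shoot meristem, had a peak of about average strength. The gene (LOC_Os03g51690) lies on chromosome 3 from 29596277 to 29606861 on the minus strand, and its peak ran from 29605487 to 29605791 (305 bp). The summit at 29605590 lay inside the gene, 1271 bp downstream of its start. Its fold was 3.39 and its −log10 q was 4.63, from 20 IP fragments over a background of 5.19. By fold it ranked 5109 of 12487 peaks. Another peak within 5 kb ran from 29595212 to 29596289, with a fold of 2.88 and a −log10 q of 3.30, and overlapped the 3′ end of OSH1 by 13 bp. It was assigned to the neighbouring gene LOC_Os03g51680. Peak numbers rose along each chromosome, and 2 numbers between these peaks had no entry, so any called peaks that carried them lay between 29596289 and 29605487, within OSH1, and were not analysed here. The other KNOX list member with a peak, LOC_Os05g03884 (a knotted-1-like homeobox gene), had a fold of 3.49, and the remaining 4 of the 6 KNOX genes had none. Among genes with a peak, 4 were described as knotted-1 homeobox or homeotic genes, and of these LOC_Os06g43860 was the strongest, with a fold of 6.82 and a summit 172 bp upstream of its start. That gene was singled out after its values were seen.

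In the monolignol list, the genes of lignin precursor synthesis, 11 of 14 genes had a peak, with a median fold of 3.66. The phenylalanine ammonia-lyase gene LOC_Os02g41650, which encodes the entry enzyme of the phenylpropanoid pathway, had a fold of 6.78 (−log10 q 20.2) with the summit 295 bp upstream of the start. LOC_Os06g44620, an AMP-binding enzyme gene entered in the list as a 4-coumarate:CoA ligase, had a fold of 5.82, 93 bp upstream. The caffeoyl-CoA O-methyltransferase gene LOC_Os06g06980 had a fold of 5.33 with its summit 1440 bp upstream, and LOC_Os02g08100, entered as another ligase of this kind, had a fold of 4.21. In the secondary wall lists, 0 of 4 secondary wall cellulose genes and 1 of 6 secondary wall regulators had a peak. The regulator was LOC_Os01g18240, a MYB factor gene, with a fold of 3.85 and a summit 55 bp upstream of its start. Among the 5 genes of the primary wall cellulose list, CESA6 (fold 3.86, summit 37 bp upstream), CESA1 (2.22) and CESA8 (2.11) had a peak. CESA2 (LOC_Os03g59340), a cellulose synthase gene outside the lists, had a fold of 3.96 with its summit 84 bp upstream. It was named after its values were seen.

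The cold list was complete. All 5 of its genes had a peak, with a median fold of 5.49. The DREB1 genes, which encode activators of the cold response, included LOC_Os09g35030 (fold 5.91, summit 1495 bp upstream) and LOC_Os09g35010 (fold 5.32). The summit of LOC_Os09g35010 lay 1825 bp downstream of the start, past the 3′ end of the gene. The remaining DREB1 gene, LOC_Os06g03670, was weaker, with a fold of 3.01, below the median of all peaks. The MYB gene LOC_Os10g41200 had a fold of 5.49 with its summit 68 bp upstream. LOC_Os02g44230, which the annotation describes only as a transcript with a conserved upstream reading frame, had a fold of 5.88. In the list of stomatal bHLH genes, 3 of 6 had a peak: LOC_Os05g51820 (fold 4.41), LOC_Os05g50900 (fold 4.35) and OsbHLH002 itself, whose peak had a fold of 1.06 over a very high background.

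Over the 7 lists together, 25 of 46 genes had a peak, and the share with a peak differed between lists by a permutation test chosen after the data were seen (p = 0.00495). Without OsbHLH002 it was 24 of 45 genes (p = 0.00401, permutation test). The monolignol list differed from both secondary wall lists combined (11 of 14 against 1 of 10, p = 0.00276 by Fisher's exact test, two-sided), a contrast also chosen after the counts were seen. Neither call held among peaks at or above the median fold, where 17 genes of the lists were left (p = 0.169, permutation test) and 7 monolignol genes (p = 0.0791, Fisher's exact test). A gene without an entry here may still be bound, since 9584 of the 22071 peak numbers had no gene in the list and each gene carried a single peak.

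**Figure D1:**
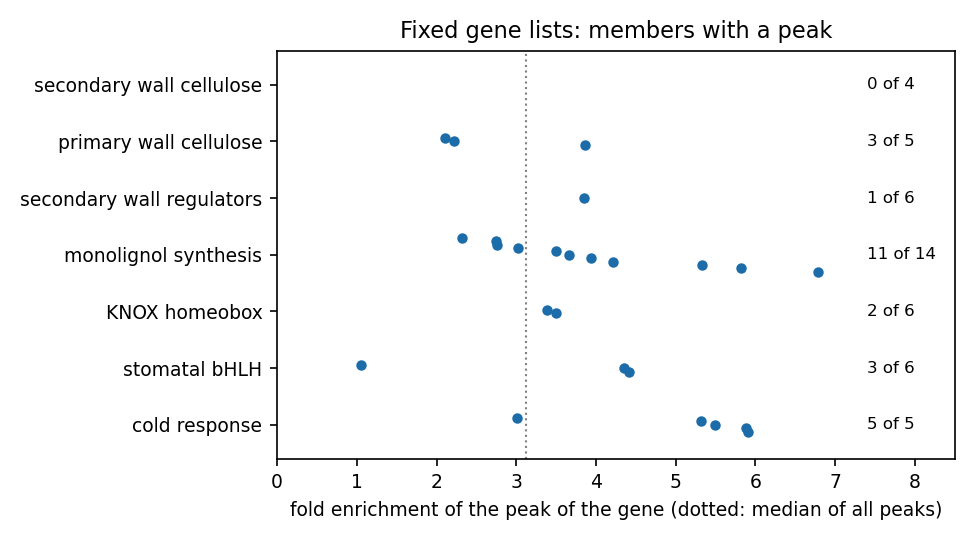
Fold enrichment (x axis, linear, IP over local background) of each list member with a peak, by gene list; each point is 1 gene, the numbers at the right give members with a peak, and the dotted line is the median of all peaks (3.13). The cold list had 5 of 5 members with a peak and the secondary wall cellulose list 0 of 4.

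The gene for OsbHLH002 itself had by far the most fragments and the lowest fold of all peaks. The gene (LOC_Os11g32100, chromosome 11, 18922046 to 18925259, plus strand) carried a peak from 18922215 to 18923038 with a fold of 1.06, the next lowest fold in the list being 1.63. The fold and p together required 34304 IP fragments at the summit (34298 to 34311 from the rounding of the fold) over a local background of 32504 (32498 to 32510). That background was 7322 times the genome-wide background and 1968 times the next highest in the list. The −log10 q was 19.6, so the IP stood above the input here by a small ratio on a very large count.

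**Figure D2:**
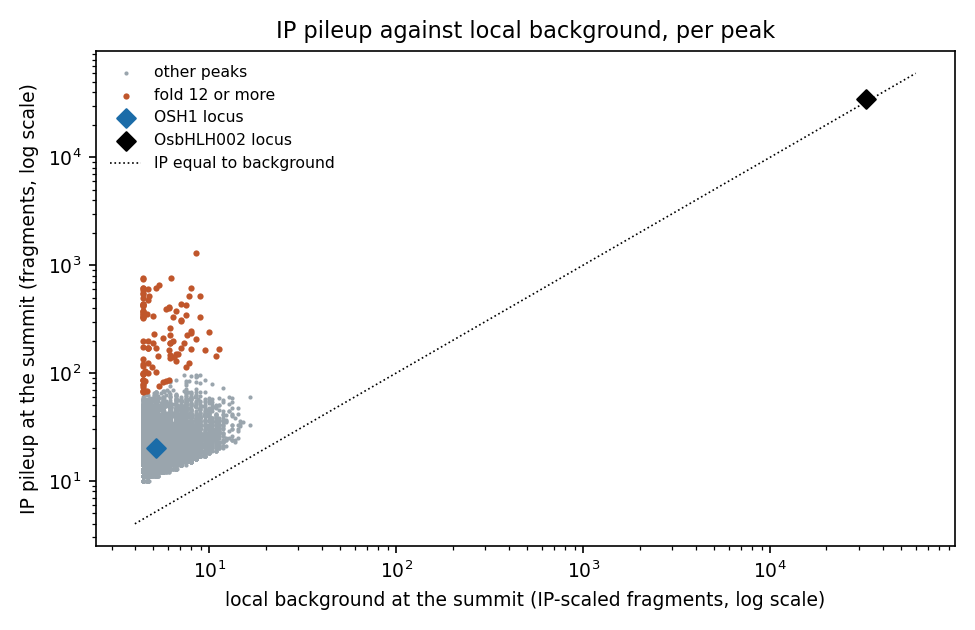
IP fragments at the summit (y axis, log scale) against local background in IP-scaled fragments (x axis, log scale), 1 point per peak. The OsbHLH002 gene (black) sits at a background of 32504 near the line of equal IP and background, OSH1 (blue) lies among the other peaks, and the 108 peaks of fold 12 or more (red) have backgrounds of at most 11.3.

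The 20 genes of highest fold with a summit in the gene or within 2 kb upstream had peaks of another kind, several kilobases wide. Their folds ran from 62.1 to 141, and their widths from 3660 to 11902 bp. The strongest was LOC_Os10g29495, a speckle-type POZ protein gene on chromosome 10, with a fold of 141 and a peak from 15323129 to 15328692. Next was LOC_Os10g28360, described as a dioxygenase of the methionine salvage pathway, with a fold of 138 and a width of 6331 bp. The wall-associated receptor kinase gene OsWAK104 (LOC_Os10g06090) had a fold of 100.008, the F-box gene OsFBX5 (LOC_Os01g17390) 79.97, the sulfate transporter gene LOC_Os10g28440 78.9 and the BTB-domain gene LOC_Os02g52314 65.3. LOC_Os07g30670, an iron-sulfur cluster protein gene, had 112, and LOC_Os07g18120, an aldehyde oxidase gene, had 67.8. LOC_Os01g10920, a peptide-N4-asparagine amidase gene, had 77.2, and LOC_Os01g09252, a WD-domain gene, had 68.8. This choice passed over 8 peaks of at least 62.1-fold with a summit elsewhere, such as that of the homeobox leucine zipper gene LOC_Os05g50130 with a fold of 99.0, picked out after its value was seen. Of these 20 genes, 4 were transposons, with LOC_Os05g13940 (fold 136, 1292 IP fragments) and LOC_Os08g34390 (fold 104) ahead of LOC_Os06g38220 (82.7) and LOC_Os05g18890 (78.9). The remaining 6 were described only as expressed or hypothetical proteins, among them LOC_Os05g06960 (fold 112) and LOC_Os10g35644 (fold 107).

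Many summits in the list lay close to gene starts, and more lay before than after them. Of 11818 peaks with a summit within 2 kb of the nearest listed gene start, 43.5% (95% exact binomial interval 42.6 to 44.4%) lay within 250 bp of it. Among peaks on a single gene it was 41.6%, and among peaks at the genome-wide background 32.5%. The share upstream of the start was 60.8% (59.96 to 61.7%, p = 1.09e-123 by an exact binomial test against an equal split). It rose with the number of IP fragments at the summit, from 47.6% among peaks of 10 to 16 fragments to 57.8% at 17 to 20, 65.4% at 21 to 26 and 77.5% at 27 or more (first against last group, p = 2.45e-136 by Fisher's exact test). Peaks whose nearest gene was a transposon were spread differently, with 19.8% within 250 bp against 44.8% for other genes (p = 6.70e-36, Fisher's exact test) and 70.3% upstream against 60.3% (p = 7.45e-07). Only peaks near a gene start were in the list, each gene kept 1 peak by a rule not given in the sources used here, and distances were taken to the nearest of a peak's genes. These shares therefore have no value for random placement to be set against, and the equal split is only a point of reference.

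**Figure D3:**
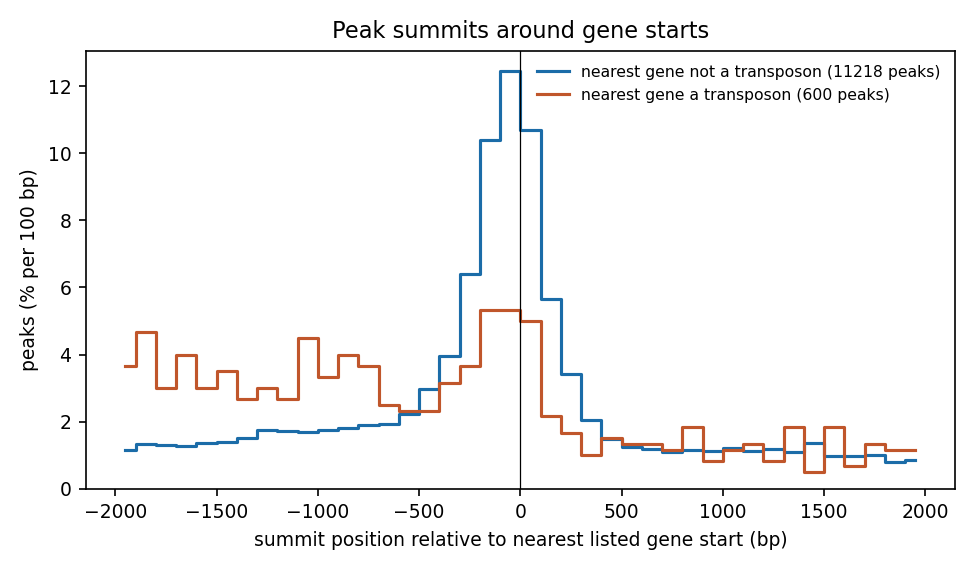
Share of peak summits per 100 bp (y axis, percent) by position relative to the nearest listed gene start (x axis, bp, negative upstream), for 11218 peaks nearest a gene that is not a transposon (blue) and 600 nearest a transposon gene (red). Summits within 250 bp of the start made up 44.8% of the former and 19.8% of the latter.

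Among genes grouped by keywords in their descriptions, receptor-like kinase genes had stronger peaks and ribosomal protein genes weaker ones than the other genes in the list. The 188 receptor-like kinase genes, which encode cell surface receptors, had a median fold of 3.51 against 3.13 for the others (permutation test, adjusted p = 0.00137). This call was lost at or above the median fold (permutation test, adjusted p = 0.143), and for summits within 2 kb upstream the mean rank difference went from 1188 to 584, among fewer genes (permutation test, adjusted p = 0.0356). OsWAK104 and OsWAK99 led them, with folds of 100.008 and 60.9. The 119 ribosomal protein genes had a median fold of 2.76 (permutation test, adjusted p = 0.00125), although LOC_Os02g18550, for the small-subunit protein S3a, reached 38.3. The 946 transposon genes had a median fold of 3.23 (permutation test, adjusted p = 0.0252), a call lost in 5 of 8 other settings and turned in direction in 1 of these. Homeobox (40 genes, median 3.52), auxin (62 genes, 3.40), zinc finger (350 genes, 3.25) and heat shock genes (61 genes, 2.94) each had an adjusted p of 0.0501. Each of these 4 classes passed in 2 of 8 other settings of the permutation test: zinc finger with pileup in place of fold (adjusted p = 0.00612) and for summits within 2 kb upstream (0.0139), homeobox with pileup (0.0393) and within bins of gene length (0.0468), and heat shock at or above the median fold (0.00484) and at a q of 0.05 or less (0.0483). AP2/ERF factor genes (91 genes, 3.51) had 0.0578. The p-values are from a two-sided permutation test of the mean rank of the fold with 100000 resamples, adjusted by Benjamini-Hochberg over 25 classes, of which 3 passed 0.05 and 8 had an unadjusted p under 0.05.

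No class of wall or hormone genes passed the test on fold. With pileup in place of fold, auxin genes (adjusted p = 0.0141, permutation test) and brassinosteroid genes (adjusted p = 0.00612, permutation test) passed, and auxin genes also passed within bins of gene length (adjusted p = 0.0468, permutation test). Pileup is not corrected for the local background. The brassinosteroid genes had a median background of 5.66, against 5.19 over all peaks. For LOC_Os03g32580 it was 16.5, the highest in the list outside the OsbHLH002 gene. The 20 cellulose synthase and synthase-like genes had a median fold of 3.34 (permutation test, adjusted p = 0.474), with CSLF6, a mixed-linkage glucan synthase gene, highest at 5.37. The medians were 2.71 for 6 laccase genes (adjusted p = 0.288, permutation test), 3.45 for 49 peroxidase genes, 3.28 for 145 glycosyl transferase genes, 2.85 for 23 expansin genes and 3.68 for 14 fasciclin-like genes. Among the other transcription factor families, none of which passed, the medians were 3.30 for 96 MYB, 3.01 for 49 NAC, 3.35 for 54 bHLH, 3.47 for 54 WRKY and 3.43 for 27 bZIP genes. With pileup in place of fold, WRKY genes had an adjusted p of 0.0393 and AP2/ERF genes of 0.0328 in the same permutation test. The 8 brassinosteroid genes had the highest median of all classes, 4.79 (adjusted p = 0.143, permutation test). All were genes of receptor kinases by description, 7 of them as BRASSINOSTEROID INSENSITIVE 1-associated receptor kinases and the other as BRASSINOSTEROID INSENSITIVE 1. Medians were 2.94 for 31 gibberellin, 3.30 for 14 cytokinin and 2.94 for 7 abscisic acid genes, and 2.85 for 11 chlorophyll or photosystem and 2.84 for 32 histone genes.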

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

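The tests on the OsbHLH002 gene and on the broad peaks were chosen only after those results were seen, and the test of upstream position was written before its result was seen.

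The input, which has no list of its own, carried a signal of its own at the gene for OsbHLH002: a local background of 32504 fragments at the scale of the IP, or about 68873 input fragments, where the genome-wide background was 4.44. The tagged protein bound there as the whole cause is argued against, because the IP stood only 1.06-fold above this background. DNA holding this sequence in excess in both libraries is consistent with a background 7322 times the genome-wide one, a value that was already known when the test was set. Whether copies of the transgene in the plant genome were the only source could not be told at this gene. They would have to number about 7727 per genome copy of the locus for the IP, and the input background was 7322 times the genome-wide one. Whether such copies were the only source, or contribute beside other DNA, stays open, since the vector sequence that would tell plant from plasmid DNA was not analysed here. The 1800 IP fragments above background may be binding, or an excess that differs slightly between the libraries, so this peak cannot be read as self-binding.

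The 108 peaks with a fold of 12 or more, 0.865% of all, held 9.96% of the summed pileup outside the OsbHLH002 gene and had a median width of 2567 bp against 443 bp for the others. Whether these regions have extra copies in the plants could not be tested on these peaks. Extra copies raise IP and input together, so choosing peaks by fold over the local background leaves out regions raised by copies alone. The median background was 1.11 times the genome-wide one, where the median fold was 29.9. The set was defined by fold and not by width: 69 of the 108 were at least 2000 bp wide, as were 169 of the other peaks. With a fragment length of 229 bp, a few fragments multiplied by PCR are argued against as the source of the whole region in these 69 wide members. Width does not test the height at the summit, where the fold was taken, so such fragments may still add to it. Narrow members, such as the peak of LOC_Os02g18550 (fold 38.3, 653 bp), are not covered by the argument from width. DNA in the IP not held by the tagged protein remains a candidate explanation: among peaks with a summit within 2 kb of a gene start, 85 of the 108 broad ones, 36.5% lay within 250 bp of it against 43.6% of the others (p = 0.227, Fisher's exact test). Over all peaks it was 28.7% against 41.3% (p = 0.0079, Fisher's exact test), but there a wide peak enters the list with its summit farther away. Neither value decides it, and no IP without the tagged protein was analysed here. Binding by OsbHLH002 over several kilobases also stays open and was not tested.

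The share of summits upstream of gene starts rose with pileup, and the input background could shape this only if it differed between the upstream and downstream sides. The median background was 5.66 within 250 bp of a start and 4.98 farther away, but upstream was not compared with downstream. Among the peaks at the genome-wide background, the groups of highest and lowest pileup still differed by 26.4 percentage points (74.8% against 48.4%, p = 9.45e-27, Fisher's exact test), which argues against that background as the whole cause. A preference of the tagged protein for sites upstream of genes is a hypothesis that stays open, beside open chromatin there, which was not measured.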

How the results depend on the processing

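Of the tests below, the settings without OsbHLH002, q at or under 0.05, without peaks of fold 12 or more, pileup in place of fold, 1 gene per peak and gene length bins, the permutation test over the gene lists, and all tests of classes, of summit positions and of the monolignol contrast, were chosen only after the data were seen, while the lists' other settings were planned. At or above the median fold, 6336 peaks and 7474 genes were left, the lists fell to 17 genes with a peak (p = 0.169, permutation test), the monolignol contrast to 7 genes (p = 0.0791, Fisher's exact test) and the OSH1 region to 1 peak, as this setting by construction keeps fewer peaks. A summit within 1 kb upstream left 5893 genes. The share of summits within 250 bp of a start was 41.7% at or above the median fold, 39.3% in the top group by fold, 41.6% for peaks on a single gene and 32.5% at the genome-wide background; the cause was not tested. The number of classes past 0.05 went from 3 to 8 with pileup in place of fold and to 5 within bins of gene length, and was 2 at or above the median fold, without peaks of fold 12 or more and with 1 gene per peak; the cause was not tested. Ribosomal protein genes passed in 8 of 8 settings (highest adjusted p 0.0423) and receptor-like kinase genes in 7 of 8, with an adjusted p of 0.143 at or above the median fold. Transposon genes passed in 3 of 8, and their mean rank difference turned from 393 to −131 (permutation test, adjusted p = 0.408) for summits within 2 kb upstream; the cause was not tested. Every motif and promoter alternative and the length-matched list test were not run, for lack of a genome and annotation of the build. No paired analysis was possible because each group had 1 library. Depth limits the weak peaks most, with pileups down to 10 fragments.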

Other observations

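The genes named here, and the tests in this part, were chosen only after the values were seen.

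Other wall-related families, grouped by their descriptions, ranged widely in fold. Of the 5 genes described as phenylalanine ammonia-lyase, LOC_Os02g41670 was the highest with a fold of 7.77 and its summit 247 bp upstream of the start. The 4 genes described as COBRA proteins, a family that acts in cellulose deposition, had a median fold of 5.11, led by LOC_Os03g18910 at 5.97. The 8 glycosyltransferase family 43 genes, a family that builds the xylan backbone, had a median of 3.79. The 6 cinnamoyl-CoA reductase genes had a median of 3.73. Of the 4 caffeoyl-CoA O-methyltransferase genes (median 5.15), LOC_Os08g38910 and LOC_Os08g38920 share the same peak, with a fold of 5.15. The median is therefore the fold of that peak, entered for each of these genes. Its summit lay inside LOC_Os08g38910, 687 bp downstream of the start. For LOC_Os08g38920 it lay 2079 bp downstream of the start, past the 3′ end of the gene. The medians were lower for the 5 CSLF genes (3.31), the 6 laccase genes (2.71) and the 5 CESA genes (2.69). The laccase genes were tested as a class above (adjusted p = 0.288, permutation test), and the other groups were not tested on their own against the other genes.

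Some genes outside the fixed lists had peaks far above the median, the first 4 of them among the broad strong peaks of fold 12 or more. The bHLH gene LOC_Os01g13460 had a fold of 40.1 with its summit 89 bp upstream, the homeobox leucine zipper gene LOC_Os06g04870 had 27.0, 20 bp upstream, and the MYB/SANT gene LOC_Os03g56234 had 26.6, 54 bp upstream. The auxin efflux carrier gene LOC_Os01g60230 had a fold of 19.3, 183 bp upstream. The brassinosteroid receptor gene LOC_Os07g40630 had 8.60, 907 bp upstream, and the peroxidase gene LOC_Os01g57730 had 9.54, 85 bp upstream.

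Genes with a peak of fold 12 or more numbered 142, and 13.4% of them were transposons against 6.36% of the other genes (p = 0.0027, Fisher's exact test). These genes lay on 108 peaks, and the test counted genes that share a peak as separate, so its p-value is too small to an unknown degree. The call for transposon genes as a class was lost with 1 gene per peak (adjusted p = 0.0558, permutation test). The 39 peaks of fold 50 or more had a median width of 5195 bp. Peaks of fold 12 or more were present on each of the 12 chromosomes, from 3 on chromosome 11 to 14 on chromosomes 1 and 4.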
